A study of Homo sapiens with 24 samples.

How the data were processed

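Transcripts of 2 prostate cancer sublines were measured by RNA-seq after siRNA against POM121. DU145DR and 22Rv1DR are described in the labels as aggressive derivatives of DU145 and 22Rv1, both human prostate cancer lines bought from ATCC. Each subline was given a control treatment, siPOM121 construct 1 or siPOM121 construct 2; the labels call the third arm Control and say no more of what it was. RNA was extracted with RNeasy kits and poly(A) libraries were made with SuperScript III and TruSeq RNA v2 reagents, per the labels' protocols. That library type does not keep the strand of origin. The 24 samples are 12 libraries read on 2 lanes each, since the sample descriptions give each library code with 2 lane numbers. Each of the 6 groups therefore holds 4 samples from 2 libraries, and nothing in the labels says that the libraries of a group came from separate cultures. The p-values measure only the spread between these libraries.

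Reads were aligned with TopHat and transcripts were quantified with Cufflinks, per the submitters' processing notes, which name the builds hg19 and mm10; the human build applies to these cells. The deposited table holds log2 FPKM (the log2 of fragments per length of transcript and per library size) with 1 value per gene symbol and sample. Before the data were examined the plan assumed plain FPKM and a pseudocount, but the values settled the unit. All 305952 values above 0, or 100% of them, turn into numbers of 6 significant digits (within 0.02 units of the sixth digit) as powers of 2, against 3.95% with base e. The smallest FPKM above the floor is 1.00, so values at or under 1 FPKM were set to 0 before deposition, and 52.8% of all values are 0. A value of 0 can stand for low expression or for an estimate that was not made, and the files do not tell these apart. The table has 27026 lines for 25277 symbols. Of these symbols 605 occur more than once, and the line with the highest mean was kept for each. Symbols are used as the table gives them, and no coordinates are printed because the annotation at hand is of another build. It was used only for gene neighbours, transcript lengths and GC content: 89.5% of symbols, and 93.1% of those above the floor in at least 1 sample, were found in GENCODE v29. Read counts and sequencing depth are not in the files. The depth per sample is unknown, so no counting interval can be given.

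The 2 lanes of each library were averaged on the log2 scale. A symbol was tested if both lanes were above the floor in at least 2 of the 12 libraries, which kept 13622 symbols. All tests were run with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with 1 mean per group, no block, a shared spread across the 6 groups (6 residual degrees of freedom) and moderated statistics with trend and robust options. They are 2-sided, and p-values were adjusted by Benjamini-Hochberg over the symbols tested, with a threshold of 0.05. Effects of siPOM121 are the mean of both constructs minus control within a line, and each construct was also compared with control and with the other. The line difference is the 22Rv1DR effect minus the DU145DR effect, tested as an interaction. SE is the moderated standard error of the log2 fold change, and n is 2 libraries per construct or control group throughout. A group FPKM is the power of 2 of the group's mean log2 value.

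Gene lists were written from general knowledge before the data were examined: 23 lists with 660 entries, of which 22 had measured members. The table holds no mitochondrially encoded genes. Each list was tested against all other genes with limma's camera at its preset correlation of 0.01 between genes, and p-values were adjusted over the lists. The same test with a correlation estimated from the libraries, and fry, which asks only whether a list's own genes move one way, were run as alternatives. In member counts, a gene rose or fell if it passed the threshold over all genes tested, and a second count was adjusted over the list alone.

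Genes are named by a rule fixed before the data were examined. It takes POM121, POM121C, E2F1, MYC and GATA2 always. It takes the 10 highest and 10 lowest fold changes past the threshold with all 4 siPOM121 libraries on one side of both controls and a mean of at least 5 FPKM over the line's 6 libraries. It takes up to 4 members per list with the smallest p, and the 5 highest and 5 lowest for the differences between lines, between constructs and between control lines. Many genes that the rule chose are all-or-none: within a line, a sample is listed at 0 and another at a log2 FPKM of 3 or more. There are 152 such symbols among those tested, 90 in DU145DR and 107 in 22Rv1DR. Library or lane values are given for some of these and no fold change of the main fit, and the rule was carried on past them to the next genes, an extension chosen after the values were seen. List medians and counts keep these genes.

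The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5 FPKM, no filter, a filter at 5 FPKM, quantile normalization, median-ratio scaling, each line fitted alone, all 24 samples as replicates, the lower-numbered lane of each library, a replicate block, each library left out in turn, plain eBayes, a 1.5-fold limit, and the other list tests. The removal of all-or-none genes, array weights and the removal of both 22Rv1DR construct 2 libraries were added after seeing the data. A pseudocount of 1 was planned for the main fit, and became an alternative once the deposited values were found to be log2 FPKM. When 1 library of a group is left out, the lone library is assumed to vary like the other groups, whose spread limma pools. The fit was tested on simulated data with 50 changed genes at each of 4 sizes among 13622 genes. For the DU145DR comparison it recovered 36%, 88%, 96% and 98% of log2 changes of 0.25, 0.5, 1 and 2, and 3.64% of its calls were false. For the 22Rv1DR comparison it recovered 28%, 88%, 100% and 96%, with 6.59% false. The list test called 1 of 1 shifted and 0 of 20 unshifted simulated lists in each line. All simulated noise, also in the draws for shared controls, was independent between genes, with 1 spread per gene over all 6 groups. These simulations therefore cannot tell how often the list test errs when genes are correlated. Nor do they cover the wider spread between the 22Rv1DR construct 2 libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. A gene that the rule chose between the control lines is left out of the text under the rules on human samples. Results for some other genes and for 1 gene list are not reported here.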

Results

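POM121, a nucleoporin anchored in the nuclear membrane, was knocked down with 2 siRNA constructs in DU145DR and 22Rv1DR, sublines of human prostate cancer cells that are used as models of docetaxel resistance. Work on POM121 in prostate cancer asks which transcripts depend on it, with E2F1, MYC and GATA2 among the factors whose nuclear import it has been tied to. Transcript levels in FPKM were read from 24 samples, which are 12 libraries on 2 lanes each. The 6 groups (control, construct 1 and construct 2 in each line) hold 2 libraries each. Libraries carry the codes 1A and 2A (control), 1B and 2B (construct 1), 1C and 2C (construct 2) in DU145DR, and 4A and 5A, 4B and 5B, 4C and 5C in 22Rv1DR. All DU145DR libraries and 4A were read on lanes 1 and 2, and the other 5 libraries on lanes 3 and 4, so the 22Rv1DR values without 4A are those from 1 pair of lanes. The depth is unknown. Each sample had 11884 to 12126 symbols above the floor of 1 FPKM in DU145DR and 12361 to 12569 in 22Rv1DR. Ribosomal protein genes held 8.61% to 9.34% of summed FPKM in DU145DR and 11.99% to 18.4% in 22Rv1DR.

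The targeted transcript fell in all 8 siPOM121 libraries. In DU145DR, POM121 stood at 21.4 FPKM in controls, 13.4 with construct 1 and 12.8 with construct 2, a mean log2 fold change of -0.71 ± 0.05 (SE, adjusted p = 5.66e-05). In 22Rv1DR it stood at 38.2, 7.75 and 7.07 FPKM, a log2 fold change of -2.37 ± 0.05 (adjusted p = 9.48e-09). The drop was larger in 22Rv1DR, with a line difference of -1.66 ± 0.07 (adjusted p = 2.84e-06). POM121C, a gene nearly identical to POM121 over much of its transcript, fell beside it: from 16.9 to 10.5 and 10.1 FPKM in DU145DR (-0.71 ± 0.06, adjusted p = 0.000108) and from 26.7 to 4.63 and 4.33 FPKM in 22Rv1DR (-2.58 ± 0.06, adjusted p = 1.88e-08). Of the 50-base windows of the longest coding POM121C transcript, 52.1% occur in POM121 transcripts, and 25.7% the other way round.

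**Figure D1:**
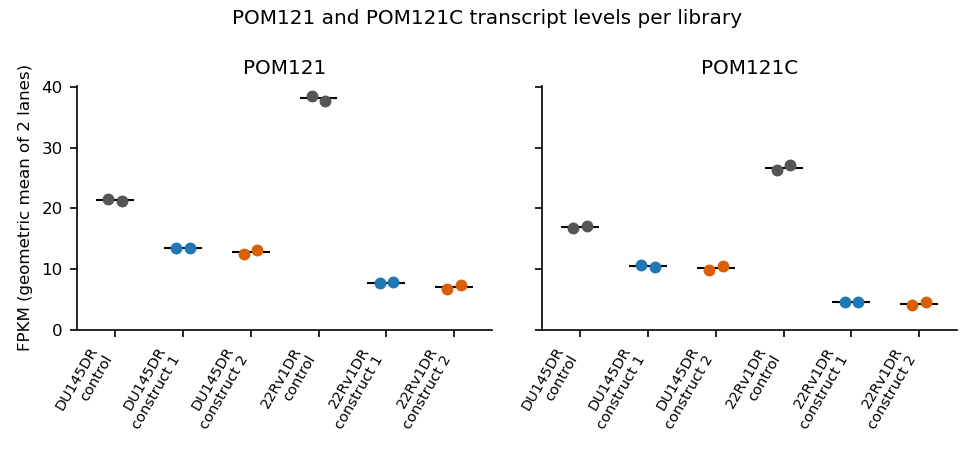
FPKM of POM121 (left) and POM121C (right) in each of the 12 libraries, by line and treatment; each point is 1 library, and the bar is the group mean of 2 libraries. POM121 control means are 21.4 FPKM in DU145DR and 38.2 in 22Rv1DR, and construct means are 13.4 and 12.8 in DU145DR and 7.75 and 7.07 in 22Rv1DR.

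In DU145DR, siPOM121 lowered 31 of the 40 measured MYC targets and raised 11 of 28 interferon response genes and 8 of 25 genes of cholesterol synthesis. These counts depend on single libraries. Fewer members passed the threshold without 1A or without 2A. Fewer MYC targets and cholesterol genes also passed when any siPOM121 library of DU145DR was left out. Without 1A and without 2A the medians kept their direction. They were -0.34 and -0.36 for MYC targets, 0.11 and 0.10 for interferon response and 0.20 and 0.15 for cholesterol synthesis. Genes that rose about 2-fold included FXYD6, a regulator of the sodium pump (log2 fold change 1.03 ± 0.07, from 4.87 to 10.5 and 9.47 FPKM), PC, the pyruvate carboxylase (1.01 ± 0.10), and DEPTOR, an inhibitor of mTOR (1.00 ± 0.08, from 8.39 to 18.3 and 15.3 FPKM). Among the genes that fell most were the cytokine IL11 (-0.88 ± 0.06, from 17.7 to 9.59 and 9.66 FPKM), NT5E, the CD73 enzyme that makes adenosine (-0.85 ± 0.07, from 15.6 to 8.20 and 9.16 FPKM), and CTGF, a matrix protein (-0.77 ± 0.10, from 50.9 to 25.9 and 34.3 FPKM). Of 13622 genes tested, 3253 differed from control, 1977 higher and 1276 lower (60.8% higher, and 51.6% with quantile normalization), of which 25 rose and 9 fell at least 2-fold and 10 were all-or-none.

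Also chosen as highest in DU145DR, PLEKHB1 rose by 0.98 ± 0.07 on the log2 scale, the surface protein CD24 by 0.94 ± 0.07 (4.22 to 7.91 and 8.33 FPKM), SNN by 0.89 ± 0.05, FKBP1B, which binds calcium release channels, by 0.88 ± 0.08, and CYBA, a subunit of the NADPH oxidase, by 0.87 ± 0.10. Adjusted p for these, PC, FXYD6 and DEPTOR ran from 2.05e-05 (SNN) to 0.000548 (CYBA). LINC00476, a long noncoding RNA that overlaps ERCC6L2, had 2.14 FPKM in controls and 5.37 and 7.80 with the constructs (1.60 ± 0.32, adjusted p = 0.00987, and 0.00247 to 0.553 over the alternatives). NBPF9 rose by 1.14 ± 0.11 (adjusted p = 0.000165, and 1.45e-06 to 0.858 over the alternatives), but stood at -0.124 on the lower-numbered lanes alone.

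Among the genes chosen as lowest in DU145DR, MARCH4, a ubiquitin ligase of membranes, fell from 14.2 to 6.75 and 8.02 FPKM (-0.95 ± 0.07), TMEM158 from 10.0 to 5.18 and 5.82 FPKM (-0.87 ± 0.08), and SNHG17, a host gene of small nucleolar RNAs, from 21.9 to 13.2 and 13.0 FPKM (-0.74 ± 0.06). LOC284454 fell by 0.78 on the log2 scale, with an SE of 0.09. Adjusted p for these, IL11, NT5E and CTGF ran from 4.6e-05 (IL11) to 0.00066 (CTGF). The small nucleolar RNAs SNORA61 (-1.13 ± 0.33, adjusted p = 0.0476) and SNORA70 (-0.73 ± 0.22, adjusted p = 0.0446) lost their calls in most alternatives, over which adjusted p ran from 0.00243 to 0.257 for SNORA61 and from 0.0277 to 0.689 for SNORA70; without 1A it was 0.257 for SNORA61.

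Of the factors named in advance, E2F1 stood at 26.0, 25.7 and 26.8 FPKM in DU145DR (log2 fold change 0.01 ± 0.06, adjusted p = 1), MYC at 115, 100.3 and 108 FPKM (-0.15 ± 0.11, adjusted p = 0.381) and GATA2 at a log2 fold change of -0.14 ± 0.11 (adjusted p = 0.389). With both construct 2 libraries of 22Rv1DR left out, the adjusted p in DU145DR was 0.0268 for MYC and 0.0349 for GATA2. The log2 fold changes stayed at -0.148 and -0.143, since those libraries enter the DU145DR comparison only through the pooled spread. With array weights the adjusted p of MYC was 0.0497. The lack of a call for MYC and GATA2 in the main fit therefore depends on the spread of 22Rv1DR libraries. Some genes were all-or-none. DOLK, of dolichol phosphate synthesis, was listed at 0 in both controls and at 18.9 to 19.6 FPKM in the siPOM121 libraries. In others the lanes of a library disagreed. NIT1 was listed at 0 on the lower-numbered lane of both controls and at 23.7 and 21.4 FPKM on the other, against 22.92 to 28.26 on the lanes with siPOM121, and IFT80, of cilia transport, at 0 and at 21.04 and 21.16, against 19.88 to 25.19. SNORA5A stood at 28.02 to 140.8 FPKM on the lanes of controls, and with siPOM121 was listed at 0 on 1 lane of 1B, 2B and 1C and at 50.05 to 135.7 on the other. TYMP and SCARNA22 were chosen too and are of this kind.

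Members of gene lists are given with log2 fold changes, and some of them lost their calls in an alternative. Every list that passed in DU145DR had fewer members called without 1A and without 2A, while its median kept its direction. Those medians were -0.10 and -0.12 for nucleoporins, and -0.13 and -0.08 for importins, exportins and Ran cycle genes. In both of these lists, and among MYC targets, fewer members were also called when any siPOM121 library of the line was left out. MYC targets had the lowest median in DU145DR: 0 rose, 31 fell and 9 did not pass (34 fell adjusted over the list alone), with a median log2 fold change of -0.33 (adjusted p = 2.48e-17, and adjusted p = 0.235 with an estimated correlation). ODC1, which begins polyamine synthesis, fell from 199 to 118 and 131 FPKM (-0.68 ± 0.06), DKC1, the pseudouridine synthase of ribosomal RNA, by 0.51 on the log2 scale (SE 0.04), GNL3 by 0.43 and RRP12 by 0.66. Nucleoporins fell in 10 of 30 cases and rose in 0 (13 fell adjusted over the list alone; median -0.10, adjusted p = 2.44e-06, and adjusted p = 0.249 with an estimated correlation). NUP188 fell by 0.38, NUP35 by 0.30 and AHCTF1 by 0.21 on the log2 scale. The list holds POM121C. Of 29 importins, exportins and Ran cycle genes, 0 rose and 11 fell (12 adjusted over the list alone; median -0.10, adjusted p = 0.000272, and adjusted p = 0.235 with an estimated correlation), among them IPO4 (-0.39), XPO5 (-0.30), TNPO3 (-0.21) and IPO5 (-0.19).

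Genes of E2F and DNA replication moved little in DU145DR: 0 of 44 rose and 10 fell (also 10 adjusted over the list alone; median -0.08, adjusted p = 0.000341, and adjusted p = 0.235 with an estimated correlation). TYMS stood at -0.23, POLE at -0.23, MCM7 at -0.19 and MCM3 at -0.16. The count of this list was smaller when any library of DU145DR was left out. Its median was -0.09 without 1A and -0.07 without 2A. In the mitosis list, 1 of 37 rose and 6 fell (1 and 5 adjusted over the list alone; median -0.07, adjusted p = 0.00666, and adjusted p = 0.582 with an estimated correlation), with the kinases PLK1 and AURKA at -0.21 each, BUB1B at -0.20 and BIRC5 at -0.18. With quantile normalization the adjusted p of the mitosis list was 0.171. Fewer mitosis genes were called when any library of DU145DR was left out. The list's median was -0.07 without 1A and -0.08 without 2A.

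The interferon response list had 11 of 28 members higher and 0 lower in DU145DR (the same counts adjusted over the list alone; median 0.12, adjusted p = 0.0038, and adjusted p = 0.235 with an estimated correlation). IFI6 stood at 0.61 ± 0.09, IFIT1 at 0.47 and STAT2 at 0.43. Without 1A and without 2A fewer interferon genes were called, and the median was 0.11 and 0.10. The count was also smaller without 1B, 1C or 2C. In the list of NF-kB and inflammatory cytokines, 8 of 20 rose and 1 fell (also adjusted over the list alone; median 0.13, adjusted p = 0.0437, and adjusted p = 0.267 with an estimated correlation). CXCL1 rose by 0.49, TNFAIP3 by 0.38 and SOD2 by 0.35, and the cytokine LIF fell by 0.47. That list's call was lost without 2A (adjusted p = 0.0529), with quantile normalization (0.0723), with the replicate block (0.062), with array weights (0.0673) and in DU145DR alone (0.116). Cholesterol synthesis and uptake had 8 of 25 higher and 0 lower (9 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.00373, and adjusted p = 0.235 with an estimated correlation). TM7SF2 rose by 0.86 ± 0.09, LSS by 0.29, and SREBF2, the transcription factor of the pathway, by 0.22. The count of cholesterol genes was smaller when any library of DU145DR was left out. The list's median was 0.15 without 2A and 0.16 without 1B. Hedgehog and Notch had 5 of 16 higher and 0 lower (the same adjusted over the list alone; median 0.15, adjusted p = 0.00874, and adjusted p = 0.235 with an estimated correlation). GLI1 rose by 0.78, NOTCH3 by 0.61 (12.4 to 19.4 and 18.5 FPKM), GLI3 by 0.26 and PTCH1 by 0.25.

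The remaining lists had an adjusted p above 0.05 in DU145DR. Of 25 p53 targets, 9 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.173). BTG2 rose by 0.74, CYFIP2 by 0.64, TP53INP1 by 0.82 and the cell cycle inhibitor CDKN1A by 0.39. Of 29 genes of the unfolded protein and ATF4 response, 8 rose and 4 fell (10 and 6 adjusted over the list alone; adjusted p = 0.427). The chaperones SDF2L1 (0.47), CALR (0.44) and PDIA4 (0.43) rose, and TRIB3, a target of ATF4, fell by 0.49. Mesenchymal and TGF-beta responsive genes split evenly, with 6 of 25 higher and 6 lower (7 and 6 adjusted over the list alone; median 0.00, mean 0.01, test direction down, adjusted p = 0.767). COL1A1 rose from 1.06 to 2.65 and 2.22 FPKM, and ANKRD1 (-0.37) and SKIL (-0.47) fell. Epithelial junctions and keratins had 6 of 25 higher and 0 lower (the same adjusted over the list alone; adjusted p = 0.165). TJP3 stood at 0.75, CLDN3 at 0.62, PKP2 at 0.37 and KRT8 at 0.25. Drug transport and docetaxel resistance had 6 of 20 higher and 0 lower (the same adjusted over the list alone; median 0.10, adjusted p = 0.0838, but 0.0472 without 1A, 0.0211 with quantile normalization, 0.033 with array weights, 0.0323 in DU145DR alone and 0.0362 with 24 samples as replicates). TUBB4A rose by 0.52, CLU by 0.48 and STMN1 by 0.32. Prostate transcription factors had 0 of 17 higher and 2 lower (also adjusted over the list alone; adjusted p = 0.24), ETV4 at -0.48 and ETV5 at -0.14.

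Hypoxia and glycolysis had 5 of 26 higher and 4 lower in DU145DR (6 and 4 adjusted over the list alone; adjusted p = 0.697). VEGFA stood at -0.37. Apoptosis regulators had 2 of 28 higher and 6 lower (3 and 7 adjusted over the list alone; adjusted p = 0.145). BCL2L11 stood at 0.45 and MCL1 at -0.17. The neuroendocrine list had 3 of 13 higher and 0 lower (the same adjusted over the list alone; adjusted p = 0.0966). NCAM1 stood at 0.54. Histones had 2 of 20 higher and 0 lower (the same adjusted over the list alone; adjusted p = 0.283), H1FX at 0.35 and H1F0 at 0.34, and ribosomal proteins 2 of 49 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.509), RPS28 and RPL28. Of 5 measured markers of stromal, endothelial and blood cells, COL1A1 rose and CD68 fell (-0.29), and 3 did not pass (adjusted p = 0.767); the count adjusted over the list alone was 1 and 1. Of these lists 9 passed the test, 4 higher and 5 lower, against 0 with an estimated correlation (limma camera) and 13 with fry.

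The responses to the constructs overlapped in DU145DR. The labels do not say what the control was, so in either line changes common to both constructs cannot be assigned to lower POM121 alone. Construct 1 changed 2700 genes and construct 2 changed 2258, and 1864 changed the same way under both, 1268 higher and 596 lower, where independent draws give 182.0 and 58.4; part of that excess may come from the shared controls, which such draws leave out. The log2 fold changes of the constructs correlated across genes at r = 0.830, against 0.514 in 20 simulated draws with the same controls and without any effect, and their covariance was 0.0578 against 0.0119. With 1 control library to each construct, so that none was shared (a test chosen after the values were seen), r was 0.582 and 0.596 for the 2 ways to do so and the covariance 0.0468 and 0.0476, against at most 0.0057 in simulated draws. Between the constructs 3 genes differed, with 725 at an unadjusted p under 0.05: ENTPD8 (-0.68, adjusted p = 0.0074), TMEFF1 (1.17, adjusted p = 0.0074) and VWA5B2 (-1.06, adjusted p = 0.0105), named after their values were seen. At the list level MYC targets (median 0.08, adjusted p = 0.0046), nucleoporins (median 0.04, adjusted p = 0.0416) and ribosomal proteins (median 0.07, adjusted p = 0.0428) were higher with construct 2, but had adjusted p values of 0.803, 0.803 and 0.902 with an estimated correlation and no member called. The count of genes was 28 without 2C, 7 without 1B and 5 without 2B, 2 without 1A, 2A or 1C, and 0 with DU145DR fitted alone. The main count of 3253 was 1551 without 1A, 1554 without 2A, and 5136 without 4C or 5C. Construct 1 gave 1384 without 1A, 1311 without 2A, 1299 without 1B, 1443 without 2B, 4627 without 4C and 4631 without 5C; construct 2 gave 1104 without 1A, 995 without 2A, 1119 without 1C, 1261 without 2C, 4134 without 4C and 4136 without 5C. Both constructs together gave 930 without 1A, 826 without 2A, 1106 without 1B, 1177 without 2B, 1053 without 1C, 1055 without 2C, 3389 without 4C and 3391 without 5C. The share higher was 61.6% for construct 1 (52.4% with quantile normalization), 66.1% for construct 2 (54.3%) and 68.0% for both constructs (55.8%).

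In 22Rv1DR, siPOM121 lowered 42 of 44 measured genes of E2F and DNA replication and 32 of 37 mitosis genes, and raised 17 of 26 genes of hypoxia and glycolysis. PDK4, which blocks pyruvate dehydrogenase, rose from 35.3 to 103 and 101 FPKM (1.53 ± 0.06, adjusted p = 1.51e-06). Among the genes chosen as highest, ATF3, a transcription factor, rose from 27.3 to 53.8 and 74.2 FPKM (1.21 ± 0.15), NR4A1 from 7.06 to 11.9 and 20.6 (1.15 ± 0.12), FOS from 5.87 to 9.59 and 15.9 (1.07 ± 0.14) and JUN from 30.8 to 57.4 and 69.4 (1.04 ± 0.09). Among those chosen as lowest, MCM3, of the replicative helicase, fell from 32.7 to 15.95 and 19.9 FPKM (-0.87 ± 0.04, adjusted p = 3.18e-06) and FEN1, the flap endonuclease, from 52.3 to 27.0 and 30.6 FPKM (-0.86 ± 0.06). Of the 13622 genes, 4842 differed from control, 2068 higher and 2774 lower (42.7% higher, but 56.6% with median-ratio scaling and 50.5% with quantile normalization), of which 41 rose and 15 fell at least 2-fold and 21 were all-or-none.

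Also chosen as highest in 22Rv1DR were SEC22C, of vesicle transport, which overlaps NKTR and SS18L2 (6.16 to 15.7 and 18.5 FPKM, 1.47 ± 0.05), CDKN1C, the p57 inhibitor of the cell cycle (4.83 to 9.44 and 11.2 FPKM, 1.09 ± 0.11), ARRDC3 (4.74 to 9.02 and 11.1 FPKM, 1.08 ± 0.09) and the GTPase RHOB (28.9 to 48.1 and 75.5 FPKM, 1.06 ± 0.10). Adjusted p for these, ATF3, NR4A1, FOS and JUN ran from 3.4e-07 (SEC22C) to 0.000668 (FOS). In 22Rv1DR fitted alone the adjusted p of ATF3 was 0.0557, the highest over its alternatives, the lowest being 3.46e-09. Also chosen as lowest were SUPT16H, a subunit of the histone chaperone FACT (54.0 to 19.05 and 32.0 FPKM, -1.13 ± 0.11), GINS4, of the replicative helicase (10.9 to 5.35 and 6.40 FPKM, -0.90 ± 0.06), FAM111B (12.7 to 6.01 and 7.81 FPKM, -0.89 ± 0.07), OAS3, an enzyme induced by interferon (9.58 to 4.44 and 6.23 FPKM, -0.86 ± 0.06), the motor protein KIF4A (14.3 to 8.07 and 7.75 FPKM, -0.86 ± 0.14), and ESYT1, of membrane contact sites (64.3 to 24.5 and 52.0 FPKM, -0.85 ± 0.09). Adjusted p for these and FEN1 ran from 1.73e-05 (OAS3) to 0.00184 (KIF4A).

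E2F1 fell in 22Rv1DR from 21.5 to 11.7 and 16.8 FPKM (-0.62 ± 0.06, adjusted p = 0.000108). MYC stood at 86.7, 79.2 and 66.6 FPKM (-0.26 ± 0.11, adjusted p = 0.097, and 0.000251 to 0.339 over the alternatives); MYC had a log2 fold change of -0.135 without 4C (adjusted p = 0.0439) and -0.377 without 5C (adjusted p = 0.000251), and its call was gained with array weights (0.0298) and with 24 samples as replicates (0.00447). GATA2 was at a log2 fold change of 0.04 ± 0.11 (not past the threshold, but 0.16 with an adjusted p of 0.0251 without 4C). Some genes were all-or-none. THAP3 was listed at 0 in controls and at 11.06 to 16.69 FPKM on the lanes with siPOM121 except 1 lane of 4B, listed at 0, and NSUN5P2, a pseudogene that overlaps POM121, at 0 and then 8.82, 8.28, 9.06 and 9.58 FPKM. TAF6, a subunit of general transcription factors, was listed at 0 on 1 lane of each control and at 59.86 and 62.83 FPKM on the other, against 36.92 to 54.29 on the lanes with siPOM121, and had a log2 fold change of -0.503 on the lower-numbered lanes alone. The chaperone DNAJB9 was listed at 0 on 1 lane of each control and at 3.90 and 3.72 FPKM on the other, against 6.14 to 12.25 on the lanes with siPOM121. RFC4, of the replication clamp loader, stood at 41.9 and 44.3 FPKM in controls, 0 in both construct 1 libraries and 41.4 and 36.0 in 4C and 5C. LENG1, SCARNA22, SNORA79, SCARNA13, PCDHGA10 and C1orf123 were chosen too and are of this kind.

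In the list of E2F and DNA replication, 1 gene rose (CCNE1, 0.19), 42 fell and 1 did not pass in 22Rv1DR (1 and 42 adjusted over the list alone), with a median log2 fold change of -0.61 (adjusted p = 7.81e-25, and adjusted p = 0.016 with an estimated correlation). MCM5 fell from 53.6 to 26.4 and 33.9 FPKM and MCM4 from 56.9 to 28.1 and 38.9. Mitosis genes fell in 32 of 37 cases and rose in 0 (34 and 0 adjusted over the list alone; median -0.43, adjusted p = 1.19e-14, and adjusted p = 0.171 with an estimated correlation). PLK1 stood at 57.5, 35.9 and 38.7 FPKM (-0.63), CENPF at -0.67, TPX2 at -0.59 and BUB1B at -0.56. MYC targets had 1 of 40 higher (LDHA, 0.13) and 29 lower (1 and 30 adjusted over the list alone; median -0.38, adjusted p = 1.49e-09, and adjusted p = 0.175 with an estimated correlation), with TCOF1, a factor of ribosomal RNA transcription, at -0.73, NOP56 at -0.52, DKC1 at -0.48 and NCL at -0.41. Nucleoporins had 0 of 30 higher and 20 lower (22 adjusted over the list alone; median -0.21, adjusted p = 2.34e-07, and adjusted p = 0.188 with an estimated correlation). NUP85 stood at -0.55, NUP188 at -0.46 and NUP107 at -0.30. Importins, exportins and Ran cycle genes had 3 of 29 higher and 13 lower (4 and 16 adjusted over the list alone; median -0.22, adjusted p = 0.0176, and adjusted p = 0.269 with an estimated correlation). IPO4 fell by 0.54, KPNB1 by 0.40 and XPO6 by 0.30, and KPNA5 rose by 0.85. Without 4A the adjusted p of that list was 0.0535.

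Hypoxia and glycolysis had 17 of 26 members higher and 0 lower in 22Rv1DR (17 and 1 adjusted over the list alone; median 0.30, adjusted p = 1.12e-07, and adjusted p = 0.171 with an estimated correlation). ALDOC rose from 51.8 to 83.3 and 78.3 FPKM, NDRG1 from 25.6 to 49.3 and 39.0, ADM from 5.08 to 8.23 and 10.4, and BNIP3L by 0.62 on the log2 scale. Of 25 p53 targets 12 rose and 4 fell (the same adjusted over the list alone; median 0.23, adjusted p = 0.000558, and adjusted p = 0.188 with an estimated correlation). The cytokine GDF15 rose from 118 to 167 FPKM with each construct, CDKN1A from 73.4 to 120.2 and 106, BTG2 by 0.83 and TNFRSF10B by 0.46. Histones had 8 of 20 higher and 1 lower (the same adjusted over the list alone; median 0.24, adjusted p = 0.0102, and adjusted p = 0.416 with an estimated correlation). HIST1H1C stood at 28.2, 53.4 and 61.5 FPKM and HIST1H1E at 1.70, 4.24 and 5.77 FPKM. The call of the histone list was lost without 4A and without 4C, with medians of 0.09 and 0.15. Poly(A) libraries select against transcripts without a poly(A) tail, so these values need not stand for all histone transcripts. Interferon response genes had 8 of 28 higher and 1 lower (the same adjusted over the list alone; median 0.05, adjusted p = 0.0298, and adjusted p = 0.24 with an estimated correlation). IFIT2 stood at 0.56, IFI6 at 0.54 and DDX60 at 0.29, and OAS3 was lower. That call was lost without 4A (adjusted p = 0.0535), without 4C (0.077) and with quantile normalization (0.068). Mesenchymal and TGF-beta responsive genes had 7 of 25 higher and 2 lower (the same adjusted over the list alone; median 0.00, mean 0.12, test direction up, adjusted p = 0.0359, and adjusted p = 0.175 with an estimated correlation). TGFB2 rose by 0.72, ITGA5 by 0.70, LOX by 0.53 and CTGF from 1.38 to 1.95 and 2.67 FPKM. That call was lost without 4A (adjusted p = 0.0599) or 4C (0.0879), with quantile normalization (0.119) or median-ratio scaling (0.106), and in 22Rv1DR alone (0.0804).

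Ribosomal proteins had 5 of 49 higher and 0 lower in 22Rv1DR (4 and 0 adjusted over the list alone; median 0.06, adjusted p = 0.0125, and adjusted p = 0.79 with an estimated correlation). RPS7 stood at 0.35, RPL15 at 0.33 and RPL13A at 0.29. Libraries 4C and 5C, both of construct 2, stood apart here: ribosomal protein genes held 18.4% and 18.3% of FPKM in the lanes of 4C and 12.3% and 11.99% in those of 5C, against 14.7% to 15.1% in controls. Without 4C, 8 ribosomal protein genes rose and 21 fell (median -0.03, adjusted p = 0.189), and without 5C 37 rose and 0 fell; the adjusted p was 0.0535 without 4A and 0.496 with quantile normalization.

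The remaining lists had an adjusted p above 0.05 in 22Rv1DR. Prostate transcription factors had 5 of 17 higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.799). ETV1 stood at 0.26, ONECUT2 at 0.22 and ETV4 at -0.46. Cholesterol synthesis and uptake had 9 of 25 higher and 5 lower (9 and 6 adjusted over the list alone; adjusted p = 0.214, and 0.0122 without 5C). LSS stood at -0.34 and EBP at -0.32. The unfolded protein and ATF4 response had 9 of 29 higher and 4 lower (10 and 4 adjusted over the list alone; adjusted p = 0.0583, but 0.000223 without 5C and 0.0213 with array weights). VLDLR stood at 0.69 and DDIT4 at 0.62. Apoptosis regulators had 7 of 28 higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.0583, but 0.0255 without 5A and 0.03 in 22Rv1DR alone): PMAIP1, the NOXA protein, rose by 0.70 and MCL1 by 0.31, and BIRC5 fell by 0.44. Drug transport and docetaxel resistance had 5 of 20 higher and 5 lower (6 and 5 adjusted over the list alone; adjusted p = 0.98). CLU stood at 0.40, ABCC5 at -0.28 and TUBB at -0.35. Epithelial junctions and keratins had 5 of 25 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.243). CLDN1 stood at 0.56 and MUC1 at -0.46. NF-kB and inflammatory cytokines had 1 of 20 higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.768), SOD2 at 0.14 and NFKB1 at -0.44. Hedgehog and Notch had 2 of 16 higher and 2 lower (the same adjusted over the list alone; adjusted p = 0.768). HES1 stood at 0.39 and NOTCH2 at -0.24. The neuroendocrine list had 1 of 13 higher and 2 lower (the same adjusted over the list alone; adjusted p = 0.98). SYT1 stood at 0.30 and SCG2 at -0.42. Of 5 markers of stromal, endothelial and blood cells 1 rose, CD68 at 0.40 (1 adjusted over the list alone; median -0.04, test direction up, adjusted p = 0.631). Of these lists 11 passed the test, 6 higher and 5 lower, against 1 with an estimated correlation and 12 with fry; without 4A 6 passed and without 4C 7.

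**Figure D2:**
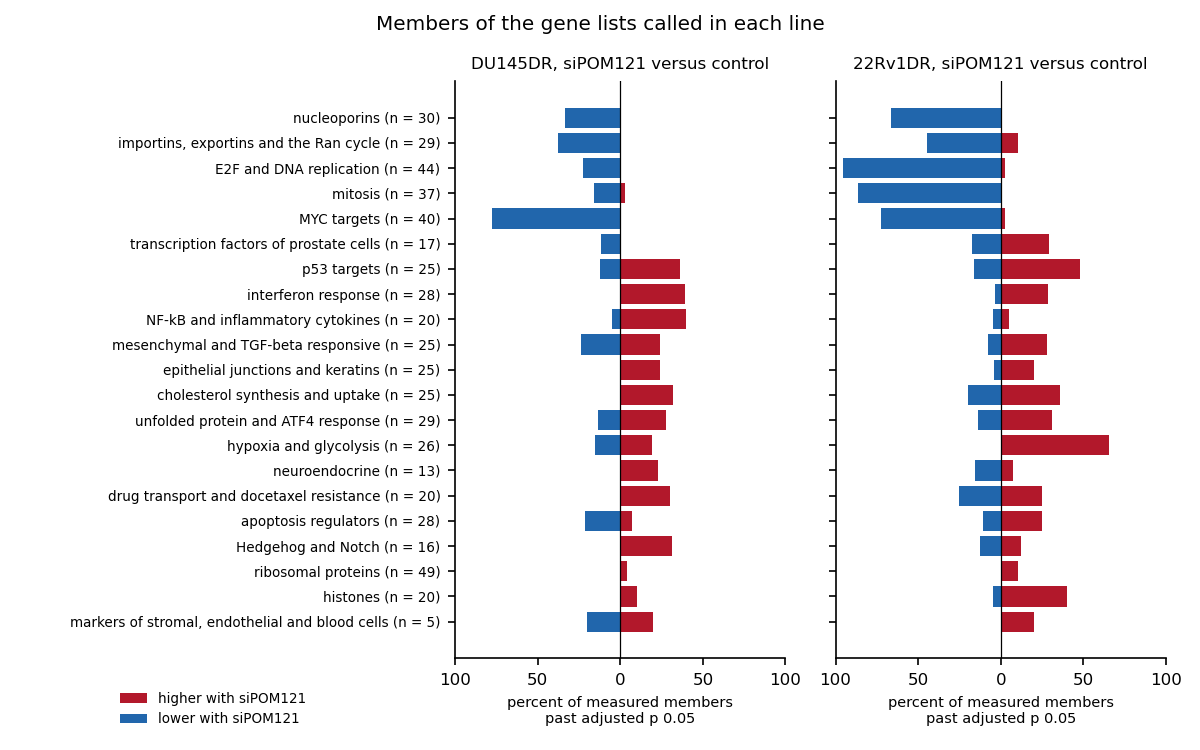
Percent of the measured members of each of 21 gene lists that passed an adjusted p of 0.05 with siPOM121 against control in DU145DR (left) and 22Rv1DR (right); bars to the right count higher members, bars to the left lower ones, and n is the number measured. Genes of E2F and DNA replication were lower in 10 of 44 cases in DU145DR and in 42 of 44 in 22Rv1DR, and MYC targets in 31 and 29 of 40.

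The constructs differed in 22Rv1DR. Genes of E2F and DNA replication had a median of -0.80 with construct 1 (1 higher, 42 lower) and -0.38 with construct 2 (0 higher, 33 lower), and 35 of the 44 were higher with construct 2 than with construct 1 (40 adjusted over the list alone; median 0.46, adjusted p = 2.55e-31, and adjusted p = 0.00849 with an estimated correlation). Mitosis genes differed the same way, with 27 of 37 higher and 0 lower with construct 2 (31 and 0 adjusted over the list alone; median 0.35, adjusted p = 3.08e-24, and adjusted p = 0.0858 with an estimated correlation), and E2F1 was higher by 0.52 (adjusted p = 0.0028, but 0.0972 in 22Rv1DR alone). G3BP2, of stress granules, stood at 46.3 FPKM in controls, 13.7 with construct 1 and 49.2 with construct 2 (1.85 ± 0.09, adjusted p = 8.34e-06), and C11orf74 at 13.6, 2.27 and 11.6 FPKM (2.36 ± 0.15, adjusted p = 8.49e-05, and up to 0.0619 over the alternatives, in 22Rv1DR alone). NBL1 (4.25, 7.73 and 2.79 FPKM, adjusted p = 0.0424) and VIL1 (3.49, 7.19 and 3.09 FPKM, adjusted p = 0.0331) lost theirs in many alternatives, over which adjusted p ran up to 1 and 0.282. ACAT2 was listed at 0 in controls and construct 1 and at 32.9 and 30.5 FPKM in 4C and 5C, TLCD1 at 33.6 to 36.8 in the other 4 libraries and at 0 in 4C and 5C, and RFC4, C1orf123 and SCARNA11 were all-or-none as well.

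The unfolded protein and ATF4 response was also higher with construct 2 than with construct 1 in 22Rv1DR (6 higher and 0 lower of 29, 11 and 0 adjusted over the list alone, adjusted p = 1.22e-05, and adjusted p = 0.641 with an estimated correlation), as were cholesterol synthesis (7 and 2 of 25, 11 and 2 adjusted over the list alone, adjusted p = 0.00151, and adjusted p = 0.356 with an estimated correlation) and histones (3 and 0 of 20, 3 and 1 adjusted over the list alone, adjusted p = 0.0413, and adjusted p = 0.793 with an estimated correlation). Epithelial junctions and keratins were lower with construct 2 (1 higher and 6 lower of 25, the same adjusted over the list alone; median -0.15, adjusted p = 0.0087, and adjusted p = 0.793 with an estimated correlation). Construct 1 changed 3697 genes and construct 2 changed 4783; 2481 changed the same way under both, 1107 higher and 1374 lower, where independent draws, without the shared controls, give 237.2 and 425.0. Their log2 fold changes correlated across genes at r = 0.649 (0.503 in 20 simulated draws) with a covariance of 0.0662 (0.0125). With 1 control library to each construct r was 0.462 and 0.5 and the covariance 0.0529 and 0.0560, against at most 0.0061 in simulated draws. Between the constructs 1577 genes differed, 994 higher with construct 2 and 583 lower. The number lower was larger with quantile normalization, as given below under the dependence on processing, so the balance depends on the scaling. With array weights, which count 4C and 5C for less, construct 1 gave 6120 genes, construct 2 gave 1532, both gave 1367, and 131 differed between the constructs. The count between constructs was 71 in 22Rv1DR alone, 223 without 4B, 315 without 5B, 5983 without 5C, and 1049 without 1A or 2A. The main count of 4842 was 2065 in 22Rv1DR alone, 2548 without 5A and, on 1 pair of lanes, 2935 without 4A. Construct 1 gave 2350 without 4A, 2086 without 5A, 1928 without 4B, 2006 without 5B, 5874 without 4C and 5875 without 5C, and construct 2 gave 2966 without 4A and 2456 without 5A. Both constructs together gave 1536 without 4A, 1244 without 5A, 1418 without 4B and 1444 without 5B. The share of called genes that were higher was 44.1% for construct 1 (58.0% with median-ratio scaling), 41.4% for construct 2 (55.4%) and 44.6% for both constructs (60.5%).

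The lines shared part of the response: 463 genes were higher in both and 576 lower in both, where independent draws give 300.1 and 259.8, and 157 and 92 moved apart (402.6 and 193.7). Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.228 and rho = 0.278. The test of the line difference called 3377 genes, 1217 with a higher log2 fold change in 22Rv1DR and 2160 with a lower one (36.0% higher, 49.0% with median-ratio scaling and 49.2% with quantile normalization). Genes of E2F and DNA replication fell further in 22Rv1DR (1 higher and 39 lower of 44, 1 and 40 adjusted over the list alone; median difference -0.58, adjusted p = 2.77e-19, and adjusted p = 0.0314 with an estimated correlation). E2F1 stood at -0.63 (adjusted p = 0.00112). Mitosis genes did so too (0 and 27 of 37, the same adjusted over the list alone; median -0.35, adjusted p = 7.87e-10, and adjusted p = 0.217 with an estimated correlation). MYC targets did not differ past the threshold (3 higher and 3 lower of 40; median 0.00, adjusted p = 0.439).

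**Figure D3:**
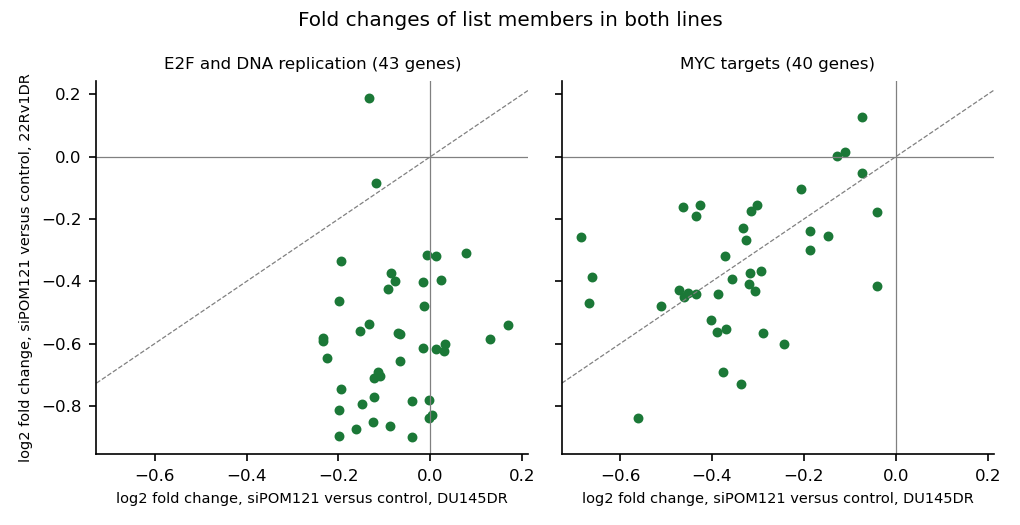
Log2 fold change with siPOM121 against control in DU145DR (horizontal axis) and 22Rv1DR (vertical axis) for 43 genes of E2F and DNA replication (left, without the all-or-none gene RFC4) and 40 MYC targets (right); each point is 1 gene and the dashed line marks equal change. The left points lie between -0.23 and 0.17 in DU145DR and between -0.90 and 0.19 in 22Rv1DR, and the right points between -0.68 and -0.04 and between -0.84 and 0.13.

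Hypoxia and glycolysis genes had a higher log2 fold change in 22Rv1DR than in DU145DR (13 higher and 0 lower of 26, 14 and 1 adjusted over the list alone; median difference 0.30, adjusted p = 5.27e-06, and adjusted p = 0.195 with an estimated correlation), as did p53 targets (6 and 3 of 25, 7 and 3 adjusted over the list alone; median 0.09, adjusted p = 0.0496, and adjusted p = 0.539 with an estimated correlation) and apoptosis regulators (6 and 3 of 28, the same adjusted over the list alone; median 0.10, adjusted p = 0.0315, and adjusted p = 0.195 with an estimated correlation). Some genes moved in opposite directions in the 2 lines: CTGF had a line difference of 1.502 (adjusted p = 0.000319), VEGFA of 0.86 (adjusted p = 0.000319), SKIL of 0.84 (adjusted p = 0.000419), SDF2L1 of -0.76 (adjusted p = 0.000186) and LSS of -0.63 (adjusted p = 0.000775). In fits of 1 line alone the changes of CTGF in 22Rv1DR (adjusted p = 0.054) and of LSS in DU145DR (adjusted p = 0.0563) were not past the threshold. The genes chosen by rule for this test (C3orf38, SNORA5A, LENG1, ACAT2 and TAF6 highest, DOLK, TMEM120A, RFC4, TLCD1 and IFT80 lowest) were all-or-none. The count of 3377 was 2111 without 1A, 1689 without 2A, 2174 without 4A, 1839 without 5A, 5135 without 4C and 6180 without 5C.

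The control groups differed widely: 11302 of 13622 genes differed between 22Rv1DR and DU145DR, 5490 higher and 5812 lower in 22Rv1DR (5961 and 5420 with median-ratio scaling), of which 2566 and 2499 differed at least 2-fold. In 22Rv1DR controls the hemoglobin genes HBA2 and HBA1 stood at 1117 and 1019 FPKM, the trypsin inhibitor SPINK1 at 848, and the heat shock protein HSPB6 at 430 FPKM; these 4 were listed at 0 in DU145DR controls. SPINT2 stood at 224 FPKM in 22Rv1DR and 1.13 in DU145DR. In DU145DR controls, UCHL1, a deubiquitinase of neurons, stood at 896 FPKM, VIM, the filament protein of mesenchymal cells, at 561, ANXA2P2 at 533 and ANXA1 at 412, where 22Rv1DR controls were listed at 0 for the first 3 and at 1.08 FPKM for ANXA1.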

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

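The tests of gene overlap, of lane disagreement, of gene overlap where the lanes agree, of a control library under a construct 2 label and of POM121C against POM121 were chosen only after the results were seen; the tests of transcript length and GC content and of other splits of the libraries were set before. A test of the line difference was past the threshold for 3377 of 13622 genes, including 48 of the genes named in advance or for the size of their change. Genes named for the size of their change in 1 line were chosen on values that this test uses again. That favours a difference, so their number is no independent support for one. Of the 48, 6 were at 0 throughout 1 line and 11 were all-or-none, and these are not given by name. The other 31 differed between the lines in their log2 fold change with siPOM121, given as the 22Rv1DR value minus the DU145DR value. Genes named only as members of a list are not among the 48, although some of them differed too, such as VEGFA (0.86), SKIL (0.84), SDF2L1 (-0.76) and LSS (-0.63).

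Genes lowered further, or raised less, in 22Rv1DR included the targets POM121 (-1.66) and POM121C (-1.86). Members of the replication and mitosis lists among them were GINS4 (-0.86), FEN1 (-0.78), MCM3 (-0.71), KIF4A (-0.69) and E2F1 (-0.63). Others were FAM111B (-1.20), OAS3 (-1.16), SUPT16H (-1.03) and ESYT1 (-0.90). Genes chosen for their rise in DU145DR had line differences of -1.98 (LINC00476), -1.43 (NBPF9), -1.25 (PC), -0.85 (PLEKHB1), -0.74 (CD24), -0.64 (DEPTOR), -0.62 (FKBP1B), -0.54 (SNN) and -0.51 (CYBA). Genes with a higher log2 fold change in 22Rv1DR were SNORA61 (1.70), CTGF (1.5), ATF3 (1.48), SEC22C (1.35), NT5E (1.06), JUN (1.04), RHOB (0.91), LOC284454 (0.83), ARRDC3 (0.82), NR4A1 (0.72) and SNHG17 (0.36). Lists that differed had medians of -0.58 (E2F and DNA replication), -0.35 (mitosis), 0.09 (p53 targets), 0.30 (hypoxia and glycolysis) and 0.10 (apoptosis regulators). With an estimated correlation their adjusted p values were, in that order, 0.0314, 0.217, 0.539, 0.195 and 0.195, so that E2F and DNA replication alone passed. The POM121 drop itself differed by 1.66 on the log2 scale between the lines, and whether a deeper knockdown or the line made the other differences cannot be separated here, since each line has 1 depth of knockdown. The construct is a further candidate. In 22Rv1DR the E2F and DNA replication list fell further with construct 1 than with construct 2. POM121 was no lower with construct 1 (7.67 and 7.84 FPKM) than with construct 2 (6.73 and 7.41 FPKM). The line difference averages both constructs and does not separate this part.

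Of 57 groups of 4 samples tested for a sample apart from the others, 2 were past Dixon's 95% critical value. Chance gives about 1 in 20 for independent samples, but these 4 are 2 libraries on 2 lanes each, so that rate need not hold here. The 2 groups were POM121 with construct 1 in 22Rv1DR, where replicate 3 stood at a log2 FPKM of 2.99, and MYC in 22Rv1DR controls, where replicate 4 stood at 6.47.

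All-or-none genes are the first pattern: 152 symbols are listed at 0 in a sample and at a log2 FPKM of 3 or more in another of the same line. Of the 82 of them with at least 300 bases and an annotation, 87.8% had another expressed gene overlapping or within 1000 bases, against 43.7% of 8589 other genes, an odds ratio of 9.26 (95% interval 4.82 to 17.8) within strata of level, and 40.1% of all-or-none genes were shorter than 300 bases against 0.19% of others. Of the genes chosen in the same way on the lower-numbered lanes alone, 75.9% (88 genes) had a library whose other lane disagreed and 28 had none, which argues against genes switched on or off in the cells as the whole cause. A candidate explanation is that the quantification gave reads of overlapping or adjoining genes, or of very short RNAs, now to one gene and now to another. For the 28 a switch in the cells stays open, and in the 19 of them with at least 300 bases and an annotation the odds ratio of such a neighbour was 24.18 (95% interval 3.28 to 178.4).

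The difference between 4C and 5C, the 2 construct 2 libraries of 22Rv1DR, is the second pattern. Their log2 values differed with an SD of 0.246 across genes, 3.21 times the 0.0767 that the lanes give, and the lanes agreed on the difference (r = 0.826). A trend with transcript length or GC content left 2.91 times that SD after its removal, which argues against it as the whole cause, although the difference did vary with GC content (rho = -0.36). Such variation was not particular to this pair. For controls rho was 0.47 between 1A and 2A and -0.47 between 4A and 5A. It was 0.24 between 1B and 2B, 0.09 between 1C and 2C and 0.26 between 4B and 5B. A control library under a construct 2 label is argued against by POM121, which stood at -2.36 log2 units from the control mean in the nearer of the pair. A difference in handling, in RNA quality or in the cells of the cultures stays open, as untested, and the array weight of 0.175 for each measures its size against 1.21 to 1.92 for the others.

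POM121C falling with POM121 is the third pattern. If POM121C transcripts were unchanged and its drop came from reads shared with POM121, it should fall less than POM121; in 22Rv1DR it fell by 0.21 more on the log2 scale (a difference of -0.21, SE 0.0349, in 4 of 4 libraries), and in DU145DR the difference was -0.0055. In 22Rv1DR this argues against an unchanged level of POM121C transcripts with shared reads added to it. If most of the POM121C value came from POM121 reads, it would fall about as far as POM121, as it did in DU145DR. The test cannot decide that case, so shared reads stay open as a cause. That the constructs may also bind POM121C transcripts stays open, since their sequences are not in the labels.

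Other splits of the 6 libraries of a line into 4 and 2 were counted, with 15 splits in each line and the real split included. The real splits call other numbers of genes here than the 3253 and 4842 reported above, so those counts are not tested directly. In DU145DR the real split called 3384 genes and the highest other split 2 (1C and 2C against the rest); in 22Rv1DR the real split called 3644 and the highest other 569 (4B and 5B against the rest). In each line 1 of the 15 splits gave as many genes, and 15 splits are too few for a share under 0.05, the smallest being 0.0667.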

How the results depend on the processing

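The removal of all-or-none genes, array weights and the removal of both 22Rv1DR construct 2 libraries were chosen after seeing the data. The plan had set log2(FPKM + 1) for the main fit. The deposited log2 values took its place after they were seen, and that scale was then run as an alternative. Across 259 pairs of a named gene and a comparison, 6407 of 6767 values under an alternative kept their direction and side of the threshold, 279 lost the call, 68 gained it and 13 reversed. The losses were uneven. With each line fitted alone 48 lost the call and 184 kept direction and side, and on the lower-numbered lanes 22 and 231. Among single libraries left out, 1A and 2A cost the most calls. Many of these genes were named because they passed in the main fit, and some alternatives could move them little. The pooled share therefore does not measure how firm a call is. The POM121 fold changes of siPOM121 against control kept direction and side in both lines in all alternatives run for single genes, as did their line difference. The 1.5-fold limit was not among those alternatives. Between the 22Rv1DR constructs the adjusted p of POM121 ran from 0.0077 to 0.505. Total counts of genes kept within 1.5 times the reported value with pseudocounts, both scalings, plain eBayes and without all-or-none genes. The pseudocounts were added to values already floored at 1 FPKM, so they could change little and do not test levels under the floor. Counts by direction moved further: with median-ratio scaling the higher genes of 22Rv1DR went from 1631 to 2498 for construct 1 and from 1107 to 1731 for both constructs, and those of the line difference from 1217 to 1836; with quantile normalization the genes lower with construct 2 than with construct 1 in 22Rv1DR went from 583 to 898. Between the DU145DR constructs, the reported 3 genes became 5 with no filter, 1 with a filter at 5 FPKM, 7 on the lower-numbered lanes and 0 in DU145DR alone. In 22Rv1DR alone the counts were 2065 for siPOM121, 1485 for construct 1, 1516 for construct 2, 71 between constructs and 903 for both. On the lower-numbered lanes 1219 genes were called with both constructs in DU145DR and 887 between the 22Rv1DR constructs. With 24 samples as replicates, which takes lanes for libraries, DU145DR had 5529, 4982 and 4606 genes for siPOM121, construct 1 and construct 2, 121 between constructs and 3722 with both; 22Rv1DR had 6049 for construct 1, 4757 between constructs and 4231 with both, and the line difference 6014. With a limit of 1.5-fold, DU145DR had 360, 394, 327 and 256 (siPOM121, construct 1, construct 2, both), 22Rv1DR 393, 498, 564 and 185, with 184 between constructs, and the line difference 630. With array weights DU145DR had 5160, 4680, 4090 and 3381, with 7 between constructs, and 22Rv1DR 6120 for construct 1, 1532 for construct 2, 131 between constructs and 1367 for both. Without both 22Rv1DR construct 2 libraries, DU145DR had 5133, 4630, 4148 and 3400 and construct 1 in 22Rv1DR 5875. Only the pooled spread changes for these comparisons in that fit, since the libraries left out enter none of their means. Comparisons that need those libraries have no value. With an estimated correlation 0 lists passed in DU145DR and 1 in 22Rv1DR. The cause was not tested where none is given.

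The replicate block took library numbers 1 and 2, or 4 and 5, as pairs, and left 3163 genes in DU145DR, 4790 in 22Rv1DR and 1 between the DU145DR constructs. The differences between libraries of a group correlated across genes at -0.067, -0.004 and 0.126 in DU145DR and -0.102, -0.047 and 0.097 in 22Rv1DR. These correlations are weak, but they cannot tell whether libraries of the same number were made together, and the labels do not say.

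Leaving out each library in turn gave 1551 (without 1A) to 5136 (4C or 5C) genes for siPOM121 in DU145DR, 1299 (1B) to 4631 (5C) for construct 1, 995 (2A) to 4136 (5C) for construct 2, 2 (1A, 2A or 1C) to 28 (2C) between constructs and 826 (2A) to 3391 (5C) for both. In 22Rv1DR it gave 2548 (5A) to 7016 (5C) for siPOM121, 1928 (4B) to 5875 (5C) for construct 1, 2456 (5A) to 7165 (5C) for construct 2, 223 (4B) to 5983 (5C) between constructs and 1244 (5A) to 3651 (5C) for both. The line difference had 1689 (2A) to 6180 (5C) genes, and the 22Rv1DR lists that passed numbered 6 (4A) to 13 (5C). The lone library is then assumed to vary like the other groups.

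Values that reversed were near 0 or all-or-none in most cases. On the lower-numbered lanes alone NBPF9 had -0.124 in DU145DR, TAF6 -0.503 in 22Rv1DR and -0.587 for the line difference, NBL1 0.032 and GATA2 -0.002 between constructs. SOX9 in DU145DR had 0.230 on those lanes. E2F1 in DU145DR had -0.034 without 2A and -0.001 without 1B (highest 0.058 without 1A), GATA2 in 22Rv1DR -0.073 without 5C (highest 0.160 without 4C), MYC 0.013 for the line difference without 4C (lowest -0.229 without 5C), GATA2 between DU145DR constructs -0.053 without 2B and -0.034 without 1C (highest 0.069 without 1B), and POM121C between the 22Rv1DR constructs 0.003 without 4C (lowest -0.195 without 5C). Depth is unknown, so what it limits cannot be said.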

Other observations

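Only values are given in this part, no test was added, and the genes were chosen after their values were seen. Under both constructs and in both lines, 186 genes were higher than in controls and 217 lower. Among the 200 lower genes left when all-or-none genes, the targets and genes under a mean of 5 FPKM in either line were taken out, the 20 with the largest smaller change of the 2 lines included the following. TRMT61A, a transfer RNA methyltransferase, stood at log2 fold changes of -0.69 in DU145DR and -0.67 in 22Rv1DR, TOE1, a trimming enzyme of small nuclear RNAs, at -0.64 and -0.80, MYBBP1A, a nucleolar protein, at -0.56 and -0.84, and the ribosome assembly factors NOL6 at -0.63 and -0.53, UTP20 at -0.66 and -0.47, NOP16 at -0.67 and -0.47 and PDCD11 at -0.46 each. PUS1, a pseudouridine synthase, stood at -0.46 and -0.59, PFAS, of purine synthesis, at -0.53 and -0.61, and MAT2A, which makes S-adenosylmethionine, at -0.57 and -0.56. Adjusted p for these genes was at most 0.00396 (MYBBP1A in DU145DR).

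Among the higher genes left by the same limits were JUNB, a subunit of AP-1, at 0.51 and 0.75, BCL6, a transcriptional repressor, at 0.54 and 0.64, CITED2 at 0.39 and 0.51, the catalase gene CAT at 0.42 and 0.44, and CROT, of peroxisomal fatty acid oxidation, at 0.41 and 0.62. Adjusted p for these genes was at most 0.000989 (CITED2 in DU145DR).

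In 22Rv1DR the alpha globin genes HBA1 and HBA2 stood at 878 to 1028 and 983 to 1121 FPKM over the 6 libraries, and HBQ1, a globin gene of the same cluster, stood at 22.1 to 32.1 FPKM. The beta globin genes HBB, HBD, HBG1 and HBG2 and the red cell genes ALAS2, KLF1, AHSP and SLC4A1 were listed at 0 in every library of both lines. ALB, the liver's serum albumin, stood at 24.03 to 28.2 FPKM in 5 of the 22Rv1DR libraries and at 7.94 in 4C.

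With construct 1 in 22Rv1DR, C11orf74, G3BP2, SUPT16H and ESYT1 were lower than with construct 2. C11orf74 stood at 16.2, 19.7 and 20.2 FPKM in DU145DR control, construct 1 and construct 2 libraries, G3BP2 at 57.0, 59.05 and 59.6, SUPT16H at 32.8, 30.4 and 30.9, and ESYT1 at 44.6, 46.2 and 46.1.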
